A study of Mus musculus with 12 samples.

How the data were processed

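RNA from hearts of C57BL/6J mice was sequenced in 12 libraries, 3 in each of sham, MI, CIH and MI+CIH, as the labels group them. The labels describe total RNA taken from frozen hearts with Trizol and name a small RNA library kit, while the design text speaks of mRNA profiles, and the values cover long messenger RNAs. The submitters' processing notes name HISAT, featureCounts 1.5.0-p3, DESeq 1.8.3 and the mouse build mm10, without saying what each was used for.

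The values deposited by the authors are FPKM (fragments or reads per kilobase of exon, scaled to library size), in 1 table of 26781 genes by 12 libraries, of which 26691 have a symbol and 1297 are at 0 in all libraries. The unit is read from the values: they are not whole, columns sum to 289085.3 to 345539.8, and for genes with few reads they are whole multiples of 1 step per gene and library. The step equals 1 read divided by the exon length and a library total, with exon lengths from GENCODE M21 on GRCm38. From it 22811 of 25404 genes with a length and a value above 0 came out as whole reads in all 12 libraries within 0.1 reads (89.8%), and library totals were 26.06 to 33.42 M reads. The totals bound counting error only: in the shallowest library 1 read on a 1 kb transcript is 0.03837 FPKM. The header names the columns by 2-digit numbers, which match the sample descriptions. No library was a copy of another.

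The test fixed beforehand was a count model, with limma on log values as its fallback for normalized values. Because the table holds FPKM the fallback was used. Log2(FPKM + 0.5) of genes at 0.5 FPKM or more in at least 3 libraries (15503) was fitted with limma 3.58.1 (limma-trend, robust, with statmod 1.5.0, in R 4.3.3), with 1 mean per group over all 12 libraries and no covariate, and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. The 6 comparisons were MI vs sham, CIH vs sham, MI+CIH vs MI, MI+CIH vs CIH, MI+CIH vs sham and the interaction (MI+CIH minus MI) minus (CIH minus sham). The labels give no batch, date or pairing. On simulated data made from the same libraries with 200 genes changed, the MI vs sham test recovered 48% of 2-fold and 83% of 4-fold changes with 6 false among 137 calls, and the interaction test 15% and 70% with 3 false among 88. Simulated genes varied independently, each with the same spread in all groups, and the changed genes had a mean of at least 1 FPKM. Real genes move together and the real groups differ in spread, so these rates may not hold for the real data.

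The groups, comparisons, gene lists, naming rule and most other settings to try were fixed before the data were examined. A few genes of the lists are counted but not reported here by name. There were 37 gene lists of cell types, pathways and secreted factors of the heart. Each was tested against the other genes with limma's camera, two-sided, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 37 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way, were alternatives. With an estimated correlation none of the 37 lists passed in any comparison. Counts of list members are given over all genes and adjusted over the list alone. Genes named are C1qtnf9, Adipoq and the receptor genes Adipor1, Adipor2 and Cdh13 in every comparison, and up to 6 that rose and 6 that fell with the smallest p, an absolute log2 change of at least 1, a mean of at least 1 FPKM, a proper symbol and full separation of the 3 libraries from the 3 (not asked for the interaction). To these come up to 4 passing members of each list or 2 values where none passed, the 5 smallest p where fewer than 5 genes passed, and in MI+CIH vs MI and the interaction any other gene that passed, the last of these chosen after values were seen. FPKM from counting without stated strand cannot part overlapping or antisense genes, so antibody gene segments and Mir5104, which may lie in a host gene, are uncertain. Positions are those of GENCODE M21 on GRCm38.

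Correlations of effects across genes used Pearson and Spearman. Relations over libraries used markers written before the test, centred within groups, with an exact permutation within groups (1296 orders) and Benjamini-Hochberg over a family of 3. This permutation and the rule that r must hold without the 2 farthest libraries replaced an unrestricted permutation of 100000 resamples after its result was seen. Those 2 were left out after centring, which was not redone, so a library left alone in its group kept its deviation. Differences of list medians have 95% bootstrap intervals over genes (10000 resamples).

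Other settings chosen beforehand were no filter, a mean of at least 1 FPKM, pseudocounts of 0.1 and 1, a fit of only the groups compared, the replicate number as a block, a minimum log2 change of 1, and leaving out each library. Added after seeing the data were median-of-ratios scaling, leaving out sham 2 and MI+CIH 3 together, and limma voom on the recovered reads (13449 genes, 86.8% of those tested). Other splits of the libraries were refitted for every count: all 10 splits of 6 libraries, or 100 regroupings of the 12 for the interaction and the correlations. Genes below the filter and the small RNA that the kit's name would imply were not analysed here.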

Results

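Heart messenger RNA was measured in C57BL/6J mice, an inbred laboratory strain, in 4 groups of 3 libraries: sham, MI, CIH and MI+CIH. The abbreviations are read here as myocardial infarction and chronic intermittent hypoxia. The hypoxia models the repeated oxygen drops of sleep apnoea. The series title names a protective protein secreted by the heart and its loss after infarction under disordered breathing in sleep. The deposited FPKM (fragments or reads per kilobase of exon, scaled to library size) covered 26781 genes, of which 15503 reached 0.5 FPKM in at least 3 libraries and were tested. Library totals recovered from the steps between FPKM values ranged from 26.06 to 33.42 M reads. Replicates correlated across genes at r from 0.961 to 0.965 in sham, 0.963 to 0.970 in MI, 0.945 to 0.961 in CIH and 0.932 to 0.941 in MI+CIH. The first principal component held 35.3% of the variance, with the MI+CIH libraries at 31.6 to 71.8, MI at 6.4 to 11.6, sham at -28.8 to -12.3 and CIH at -43.6 to -31.6. MI+CIH 3 lay farthest out at 71.8. On the second component, with 12.1% of the variance, CIH 1 lay at 23 against -38.6 and -29.7 for CIH 2 and 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all 12 libraries, and none of these 4 tested members of the sex-linked list passed the limma test in the 6 comparisons. All values below are means ± SD of n = 3 libraries in FPKM, and changes are log2 fold changes. The p-values measure the spread between libraries labelled as separate samples, and the labels do not say whether each came from its own animal.

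The best known candidate for the protein of the title is CTRP9, a secreted relative of adiponectin made by heart muscle, encoded by C1qtnf9 (ENSMUSG00000071347, chromosome 14, 60768134 to 60780869, GRCm38). C1qtnf9 stood at 47.6 ± 4.38 in sham, 37.4 ± 4.01 in MI, 55.5 ± 14 in CIH and 38.3 ± 9.42 in MI+CIH. Its log2 fold change was -0.35 in MI vs sham (limma adjusted p = 0.456) and 0.19 in CIH vs sham (0.766). It was 0.01 in MI+CIH vs MI (0.984), -0.52 in MI+CIH vs CIH (0.0937) and -0.34 in MI+CIH vs sham (0.311). None of these passed at this number of libraries, and in MI+CIH vs CIH the gene passed without CIH 1 (-0.75, adjusted p = 0.0193) and without MI+CIH 2 (0.0335), as it did after median-of-ratios scaling (0.0379) and by voom (0.0221). Its range over alternatives was 0.0193 to 0.329, and its interaction of MI and CIH was -0.17 (adjusted p = 0.783). Adiponectin itself, Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028), a hormone of fat cells, rose by 4.30 in MI+CIH vs CIH (adjusted p = 0.0026) and by 3.31 in MI+CIH vs sham (0.0113). Its receptor gene Adipor2 rose by 0.61 (0.023) and 0.59 (0.0385). The other receptor genes Adipor1 and Cdh13 (T-cadherin) passed in none of the 6 comparisons. Adipoq moved with other fat cell genes and with the library: it stood at 17.5 in sham 2 against 2.33 and 2.17 in the other sham libraries, at 14.5 to 28.6 in MI and at 41.2 to 70.1 in MI+CIH.

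**Figure D1:**
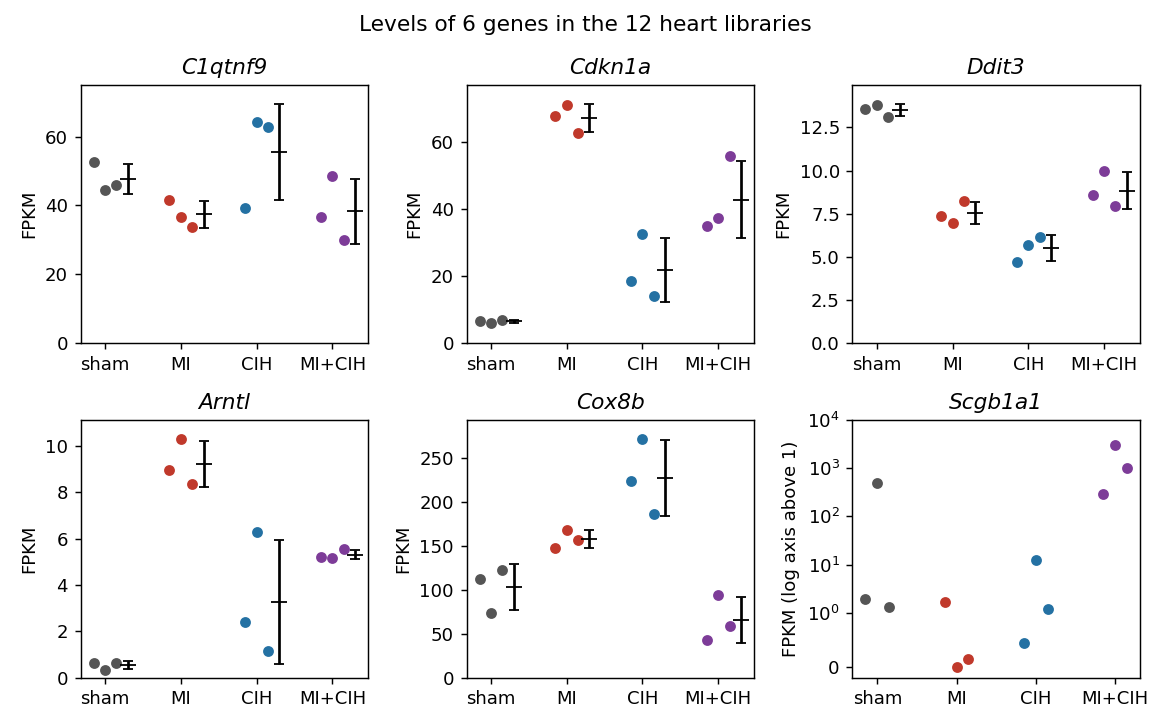
Levels of 6 genes in FPKM (vertical axis) in the 12 libraries by group, 1 point per library, with the group mean ± SD drawn beside the points except for Scgb1a1, whose axis is logarithmic above 1. Cdkn1a lies at 62.9 to 71.2 in MI against 6.06 to 6.91 in sham, Ddit3 at 4.69 to 6.14 in CIH against 13.1 to 13.8 in sham, and Scgb1a1 at 290 to 2980 in MI+CIH and 485 in sham 2.

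MI vs sham asked what infarction did without hypoxia. Of the 42 tested collagen and matrix genes of the scar 28 rose and 0 fell, and the list passed camera but not with an estimated correlation (adjusted p = 0.215). Among them were Col3a1, a fibrillar collagen of scars (2.62, 29.6 ± 7.79 in sham and 186 ± 53.9 in MI, ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), Eln, which encodes elastin (2.17), and Mfap5, a microfibril protein (1.99). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the cell cycle inhibitor p21, rose from 6.5 ± 0.427 to 67.3 ± 4.16 (log2 3.28, SE 0.26, adjusted p = 0.000712). Arntl, the clock activator BMAL1 (3.22, ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), and Nfil3, a clock repressor (2.43), rose, while the clock output gene Hlf (-1.76) and the repressor gene Nr1d2 (-1.84) fell. The labels give no collection time, so time of day cannot be told apart from an MI effect for these clock genes. Cdkn1a stood at 18.5, 32.5 and 14.1 in CIH 1, 2 and 3, in the order of Arntl (2.42, 6.26 and 1.14). Whether time of day bears on Cdkn1a was not tested. Of 9 red cell genes 5 fell, with Bpgm (-1.96), which sets how firmly red cells hold oxygen, among them.

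Further genes that rose with full separation of the libraries were Abra (2.20), an actin-binding protein of striated muscle, and Slc38a2 (1.42), an amino acid transporter. The antibody gene segments Igkv15-103 (4.24) and Ighv7-1 (3.37) rose too but are uncertain, because such segments share reads with near copies. Those that fell were Scn4b (-2.40), a sodium channel subunit, Mid1ip1 (-2.13), a regulator of fat synthesis, and the protease gene Adamts7 (-1.11). Slc25a37, which carries iron into mitochondria, fell from 19.1 ± 7.93 to 4.85 ± 0.467. Chance would separate 3 libraries from 3 others in this way in 10% of genes.

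The collagen list had a median of 1.78 (camera adjusted p = 3.97e-35, adjusted p = 0.215 with an estimated correlation), and 42 genes rose when adjusted over the list alone. Activated fibroblast genes rose in 5 of 22 cases (13 adjusted over the list alone), with Postn, a matrix protein of scar fibroblasts (2.28), and Ltbp2 (2.87). The fibroblast median was 0.69 (camera adjusted p = 4.09e-08, adjusted p = 0.215 with an estimated correlation). Matrix proteases and inhibitors rose in 4 of 19 (11 adjusted over the list alone), with Adamts4 (2.17) and Mmp2 (1.66). The protease median was 0.77 (camera adjusted p = 4.84e-08, adjusted p = 0.215 with an estimated correlation). In the cardiac stress list 3 of 19 rose (8 adjusted over the list alone): Ccn2 (1.95), Rcan1 (1.68), a calcineurin regulator, and Fhl1 (0.77). The stress median was 0.77 (camera adjusted p = 6.86e-07, adjusted p = 0.215 with an estimated correlation). Atrial genes varied between libraries beside it: Bmp10, an atrial growth factor, stood at 126, 0.0583 and 4.21 in MI 1, MI 2 and MI 3. Secreted heart factors rose in 7 of 25 (9 adjusted over the list alone), with Sfrp2 (3.03), a Wnt modulator, Angptl4 (2.82), an inhibitor of lipoprotein lipase, and Fstl1 (1.56). The secreted factor median was 0.68 (camera adjusted p = 0.000685, adjusted p = 0.5 with an estimated correlation). Glucocorticoid response genes rose in 5 of 21 (13 adjusted over the list alone), with Fkbp5 (1.64) and Errfi1 (1.38). The glucocorticoid median was 0.87 (camera adjusted p = 2.68e-08, adjusted p = 0.215 with an estimated correlation). In the endoplasmic reticulum stress list 5 rose and 1 fell of 24 (15 and 1 adjusted over the list alone). Manf (1.24), Pdia4 (0.87) and Pdia6 (0.83), which help fold secreted proteins, rose, and Ddit3, the stress transcription factor CHOP, fell (-0.81). The reticulum stress median was 0.59 (camera adjusted p = 1.46e-07, adjusted p = 0.274 with an estimated correlation).

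Erythroid genes had a median of -2.25 (camera adjusted p = 5.04e-11, adjusted p = 0.215 with an estimated correlation), and 8 of 9 fell adjusted over the list alone. The haemoglobin gene Hba-a1 stood at 385, 373 and 129 in the sham libraries and at 39.8 to 41.6 in MI. Another haemoglobin gene, Hbb-bs, overlapped between the groups, at 139, 142 and 81.5 in sham and 84.4, 79.6 and 64.6 in MI. Of 19 clock genes 3 rose and 6 fell (4 and 10 adjusted over the list alone). The clock median was -0.61 (camera adjusted p = 0.000685, adjusted p = 0.215 with an estimated correlation). Of 32 cardiomyocyte genes 0 rose and 2 fell (2 adjusted over the list alone), Tcap (-2.07), a protein of the sarcomere's Z-disc, and the splicing factor gene Rbm20 (-0.59). The cardiomyocyte median was -0.15 (camera adjusted p = 8.41e-05, adjusted p = 0.579 with an estimated correlation). In the renin and adrenergic list of 16 genes 3 rose and 2 fell (4 and 2 adjusted over the list alone). Agt, encoding angiotensinogen, rose from 2.79 ± 0.41 to 11.4 ± 4.67, and the receptor genes Agtr1a (-0.90) and Adrb1 (-1.21) fell. The renin list's camera adjusted p was 0.453. Macrophage genes rose in 1 of 30 (3 adjusted over the list alone), namely Adgre1, which encodes F4/80 (0.98). The macrophage median was 0.59 (camera adjusted p = 2.76e-05, adjusted p = 0.659 with an estimated correlation). HIF targets rose in 2 of 32 (6 adjusted over the list alone), Angptl4 and P4ha1 (0.79), a collagen hydroxylase. The HIF target median was 0.30 (camera adjusted p = 0.0213, adjusted p = 0.579 with an estimated correlation).

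Single members of other lists rose. Ppargc1a (0.81) did so among 28 fatty acid oxidation genes (2 adjusted over the list alone, median -0.16, camera adjusted p = 0.0213, adjusted p = 0.673 with an estimated correlation). Nox4 (1.49), which makes hydrogen peroxide, did so among 8 NADPH oxidase genes (2 adjusted over the list alone, median 0.35, camera adjusted p = 0.0476, adjusted p = 0.673 with an estimated correlation). Myc (1.24) was the single gene that rose among 24 immediate early genes (7 adjusted over the list alone, median 0.42, camera adjusted p = 0.0201, adjusted p = 0.673 with an estimated correlation). Cdkn1a was the single gene that rose among 26 apoptosis and p53 targets (1 adjusted over the list alone, median 0.28, camera adjusted p = 0.0283, adjusted p = 0.659 with an estimated correlation). The chemokine gene Ccl11 (-1.56) and Csf1 (-0.73) fell among 28 cytokine genes (2 adjusted over the list alone, where 2 rose, camera adjusted p = 0.193). Gbp5 (-0.88) fell among 37 interferon response genes (1 adjusted over the list alone, camera adjusted p = 0.409).

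No member passed among 19 adipocyte genes (1 adjusted over the list alone, median 0.80, camera adjusted p = 0.00302, adjusted p = 0.673 with an estimated correlation) or 12 epicardial genes (median -0.50, camera adjusted p = 0.0276, adjusted p = 0.673 with an estimated correlation). The same held for 16 lists with camera adjusted p from 0.0529 to 0.753. Their medians were 0.06 for nuclear oxidative phosphorylation, -0.37 for mitochondrially encoded proteins, -0.40 for neutrophil, 0.38 for lymphocyte and 0.24 for MHC class II genes. They were 0.24 for endothelial, 0.02 for smooth muscle and pericyte, -0.41 for atrial, 1.15 for skeletal muscle, -0.57 for lung and -0.12 for nerve genes. The remaining medians were -0.07 for the oxidative stress response, 0.35 for cell cycle, 0.52 for C1q and TNF related, 0.06 for heat shock and 0.10 for sex-linked genes. Among them 3 endothelial genes and 4 C1q and TNF related genes passed when adjusted over the list alone. The skeletal muscle myosin gene Myh4 stood at 30.2 in MI 2 and at 0.0054 and 0.194 in the other MI libraries.

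By limma 304 of 15503 genes changed (212 rose, 92 fell), and the share that rose was 69.7%, or 59.4% after median-of-ratios scaling. The count was 22 without MI 3, 30 without MI 2, 139 without MI 1, 30 without sham 1, 27 without sham 2, 484 without MI+CIH 3 and 65 without both sham 2 and MI+CIH 3. Of these sham 2 held genes of the airway, and MI+CIH 3 lay farthest out on the first principal component.

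CIH vs sham asked what hypoxia did in hearts without infarction. A single gene passed, Ddit3 (ENSMUSG00000025408, chromosome 10, 127290774 to 127296288), which encodes CHOP, a transcription factor of the unfolded protein response that promotes cell death. It fell from 13.5 ± 0.364 to 5.5 ± 0.741 (log2 -1.23, SE 0.13, adjusted p = 0.0115, lower in 3 of 3 libraries). The next genes by p did not pass: Gbp5, an interferon-induced GTPase (-1.38), Maco1 (-0.71), Mid1ip1 (-1.45) and the collagen gene Col5a3 (1.44), all with adjusted p = 0.0869. Nuclear oxidative phosphorylation genes lay higher as a list (adjusted p = 0.53 with an estimated correlation), with Cox8b, a heart and muscle subunit of cytochrome oxidase, at 103 ± 26.1 in sham and 228 ± 43.4 in CIH (1.16, adjusted p = 0.222). Interferon response and epicardial genes lay lower as lists (adjusted p = 0.53 and 0.53 with an estimated correlation), with 0 members passing over all genes.

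Nuclear oxidative phosphorylation had a median of 0.47 (camera adjusted p = 1.57e-17, adjusted p = 0.53 with an estimated correlation). There 39 of 41 genes were above 0, and 2 rose adjusted over the list alone against 0 over all genes. RNA composition differed too: the short RNA Rpph1 made up 3.26 to 4.97% of FPKM in sham and 5.1, 9.26 and 8.08% in CIH 1, 2 and 3. Mitochondrial genes held 11.01 to 11.52% of recovered reads in sham and 14.45, 7.42 and 6.11% in CIH 1, 2 and 3. Fatty acid oxidation genes (1 rose adjusted over the list alone and 0 over all genes, median 0.43, camera adjusted p = 2.78e-11, adjusted p = 0.53 with an estimated correlation) included Pdk4, a brake on glucose oxidation (2.34, adjusted p = 0.187). Interferon response genes fell in 20 of 37 cases adjusted over the list alone and in 0 over all genes, with Gbp4 at -1.48 (adjusted p = 0.117). The interferon median was -0.69 (camera adjusted p = 2.12e-16, adjusted p = 0.53 with an estimated correlation). Epicardial and mesothelial genes fell in 8 of 12 adjusted over the list alone and in 0 over all genes, with Muc16 at -1.30 and Lrrn4 at -1.70. The epicardial median was -1.32 (camera adjusted p = 2.03e-07, adjusted p = 0.53 with an estimated correlation). Erythroid genes fell in 6 of 9 adjusted over the list alone and in 0 over all genes (median -1.27, camera adjusted p = 2.7e-05, adjusted p = 0.53 with an estimated correlation). Hba-a1 stood at 29.1, 103 and 94.3 in CIH 1, 2 and 3 against 129 to 385 in sham. Hbb-bs stood at 37.9, 162 and 150 against 81.5 to 142, so it was not lower in CIH 2 and 3. Lymphocyte genes fell in 2 of 16 adjusted over the list alone and in 0 over all genes, with Igkc, the kappa light chain, at -3.46. The lymphocyte median was -0.38 (camera adjusted p = 0.0019, adjusted p = 0.53 with an estimated correlation).

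Cytokine genes fell in 2 of 28 adjusted over the list alone (median -0.29, camera adjusted p = 0.000499, adjusted p = 0.632 with an estimated correlation). Clock genes rose in 1 and fell in 4 of 19 adjusted over the list alone (median -0.49, camera adjusted p = 0.0125, adjusted p = 0.53 with an estimated correlation). Endoplasmic reticulum stress genes rose in 7 and fell in 1 of 24 adjusted over the list alone (median 0.20, camera adjusted p = 4.65e-05, adjusted p = 0.53 with an estimated correlation). Glucocorticoid response genes rose in 7 and fell in 1 of 21 adjusted over the list alone (median 0.14, camera adjusted p = 0.000171, adjusted p = 0.53 with an estimated correlation). Of these 4 lists Ddit3 alone passed over all genes. Collagens (median 0.14, camera adjusted p = 0.0125, adjusted p = 0.956 with an estimated correlation) lay slightly higher, with 0 passing either way. Without both sham 2 and MI+CIH 3 the collagen median was 0.05 and the glucocorticoid median 0.28. Atrial genes (median -1.04, camera adjusted p = 0.0321, adjusted p = 0.878 with an estimated correlation) moved with the library. Nppa, the natriuretic peptide gene, stood at 243, 1550 and 414 in the CIH libraries against 1140 to 2040 in sham. Arntl also differed within the group, at 2.42, 6.26 and 1.14.

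At an unadjusted p under 0.05 there were 1836 genes where 775.2 are due by chance, and limma voom on the recovered reads gave 16 genes. The count was 124 without CIH 1, 11 without sham 3, 10 without MI+CIH 3 and 2 without MI 1. It was 0 without CIH 2, without sham 1 and without sham 2, where Ddit3 no longer passed (adjusted p = 0.0786, 0.122 and 0.132, range over alternatives 0.00811 to 0.132). It was also 0 with only these 2 groups in the fit, with the replicate number as a block, and without both sham 2 and MI+CIH 3 (0.13, 0.0777 and 0.099).

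MI+CIH vs MI asked what hypoxia added in infarcted hearts. Bpifb1 (5.68) and Muc5b (3.60), products of airway secretory cells, and Foxj1 (3.02), the master regulator of motile cilia, rose. In separate sets of airway markers 5 of 10 secretory and 0 of 13 tested ciliated ones rose, the ciliated set not holding Foxj1. Reg3g (4.40), an antibacterial lectin, and Cxcl17 (3.93), a mucosal chemokine, rose as well. Others that rose were Marco (2.86), a macrophage scavenger receptor, Gpnmb (2.56), Itgax (1.34), which encodes CD11c, Pglyrp1 (2.82), Basp1 (1.77, ENSMUSG00000045763, chromosome 15, 25363277 to 25413764) and Tmsb10 (1.96). Ppargc1a (-1.15), the coactivator PGC-1 alpha that drives mitochondrial gene expression, Tfrc (-2.30), the transferrin receptor, and Tmem246 (-1.30, ENSMUSG00000039611, chromosome 4, 49584506 to 49597876) fell. The secretory airway gene Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958) stood at 290, 2980 and 990 in the MI+CIH libraries, at 0 to 1.71 in MI and at 485 in sham 2, where 23 of the 37 genes that rose here were also above both other sham libraries.

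Also higher were Col2a1 (3.01) and Acan (2.14), known from cartilage (0 of 7 other tested cartilage markers passed), the clock repressor gene Nr1d1 (1.59), Pfkfb3 (1.19), an activator of glycolysis, Anxa8 (2.03), and Cd5l (1.74), a macrophage product. Also lower were the deubiquitinase gene Otud1 (-1.72), the transcription cofactor gene Cited4 (-1.61), Gpr4 (-1.13), a proton-sensing receptor of endothelium, Myot (-0.90), a Z-disc protein, and Slc38a2 (-0.88).

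Nuclear oxidative phosphorylation genes had a median of -0.58 (camera adjusted p = 6.67e-18, adjusted p = 0.511 with an estimated correlation), and 24 of 41 fell adjusted over the list alone against 0 over all genes. Cox8b (ENSMUSG00000025488, chromosome 7, 140898945 to 140900446) stood at 158 ± 10.2 in MI and 65.1 ± 26.2 in MI+CIH (-1.34, adjusted p = 0.0581). Cardiomyocyte genes rose in 1 and fell in 16 of 32 adjusted over the list alone and in 0 over all genes, with Ryr2, the calcium release channel, at -0.70 (adjusted p = 0.0789). The cardiomyocyte median was -0.62 (camera adjusted p = 4.33e-11, adjusted p = 0.511 with an estimated correlation). Fatty acid oxidation genes fell in 1 of 28, Ppargc1a, and in 3 adjusted over the list alone (median -0.48, camera adjusted p = 1.92e-08, adjusted p = 0.511 with an estimated correlation). Heat shock genes fell in 5 of 22 adjusted over the list alone and in 0 over all genes (median -0.40, camera adjusted p = 7.4e-07, adjusted p = 0.511 with an estimated correlation). Endothelial genes fell in 3 of 23 adjusted over the list alone and in 0 over all genes (median -0.27, camera adjusted p = 0.000501, adjusted p = 0.511 with an estimated correlation). Immediate early genes (median -0.34, camera adjusted p = 0.0222, adjusted p = 0.766 with an estimated correlation) lay lower with no member passing. HIF targets split, with Pfkfb3 up and Tfrc down (1 and 8 adjusted over the list alone, median -0.13, camera adjusted p = 0.00478, adjusted p = 0.511 with an estimated correlation).

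Cell cycle genes rose in 13 of 28 adjusted over the list alone and in 0 over all genes, with Ccna2, cyclin A2, at 1.18 (adjusted p = 0.0581). The cell cycle median was 0.62 (camera adjusted p = 1.18e-06, adjusted p = 0.511 with an estimated correlation). Macrophage genes rose in 1 of 30, Gpnmb, and in 6 adjusted over the list alone (median 0.66, camera adjusted p = 5.16e-07, adjusted p = 0.527 with an estimated correlation). Lung genes rose in 1 of 8, Foxj1, and rose in 7 and fell in 1 adjusted over the list alone (median 2.86, camera adjusted p = 0.000129, adjusted p = 0.511 with an estimated correlation). Epicardial genes rose in 6 of 12 and lymphocyte genes in 4 of 16 adjusted over the list alone, and 0 of either over all genes. The epicardial median was 0.87 (camera adjusted p = 0.000429, adjusted p = 0.527 with an estimated correlation). The lymphocyte median was 0.62 (camera adjusted p = 0.000875, adjusted p = 0.511 with an estimated correlation). Collagens (median 0.55, camera adjusted p = 3.04e-05, adjusted p = 0.694 with an estimated correlation) and activated fibroblast genes (median 0.48, camera adjusted p = 0.00542, adjusted p = 0.572 with an estimated correlation) lay higher with no member passing. So did neutrophil (median 1.90, camera adjusted p = 0.00542, adjusted p = 0.527 with an estimated correlation) and cytokine genes (median 0.46, camera adjusted p = 0.00542, adjusted p = 0.627 with an estimated correlation). MHC class II genes (2 adjusted over the list alone, median 0.40, camera adjusted p = 0.0101, adjusted p = 0.527 with an estimated correlation) rose in 1 of 15, Itgax. NADPH oxidase (3 higher adjusted over the list alone, median 0.65, camera adjusted p = 0.00542, adjusted p = 0.527 with an estimated correlation), oxidative stress (5 higher and 1 lower adjusted over the list alone, median 0.40, camera adjusted p = 0.0277, adjusted p = 0.7 with an estimated correlation) and adipocyte genes (median 0.46, camera adjusted p = 0.0441, adjusted p = 0.797 with an estimated correlation) lay higher with no member passing over all genes. MI+CIH 3 stood apart in several of these groups: S100a9, a neutrophil protein, was at 92.6 against 8.38 and 0.608 in MI+CIH 1 and 2, and the metallothionein gene Mt2 at 787 against 129 and 76.4. The myosin gene Myh7 was at 2350 there against 355 and 138, and Myh6 at 1210 against 4390 and 4070. Without both sham 2 and MI+CIH 3 the medians of 9 of the 20 lists that passed camera moved by over 1.5 times: cell cycle to 0.28, cytokine to 0.17, neutrophil to 0.92, macrophage to 0.38, oxidative stress to 0.22, NADPH oxidase to 0.38, cardiomyocyte to -0.41, heat shock to -0.23 and HIF target genes to -0.24.

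By limma 51 genes changed (37 rose, 14 fell), with a smallest adjusted p of 0.0474, and the share that rose was 72.5%, or 52.6% of 76 genes after median-of-ratios scaling. The count was 1029 without MI+CIH 2, 101 without CIH 1, 85 without MI+CIH 1, 8 without sham 3, 10 without both sham 2 and MI+CIH 3, and 0 without any 1 of sham 1, MI 1, MI 2, MI 3, CIH 2, CIH 3 and MI+CIH 3 (2934 genes had an unadjusted p under 0.05 in all 12 libraries). Voom turned the balance, with 206 genes of which 76 rose and 130 fell (36.9% rose).

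MI+CIH vs CIH asked what infarction did under hypoxia. Scar genes rose almost throughout (41 of 42 collagen and matrix genes), with Eln (2.78), Tnc, the matrix protein tenascin C (2.61), and Col14a1 (2.62). Immune genes rose in 28 of 30 macrophage markers, with Spp1, osteopontin (5.63), and Gpnmb (3.31). Airway tissue may have come with the MI+CIH hearts, where Scgb1a1 stood at 290 to 2980 against 0.448 to 12.6 in CIH. How far such tissue adds to the macrophage, lymphocyte and epicardial genes was not tested, here or in the other comparisons with MI+CIH. Nuclear oxidative phosphorylation genes fell in 36 of 41 cases, with Cox8b (-1.86), Atp5g3 (-1.29), an ATP synthase subunit, and Ndufs1 (-1.10) of complex I. Fatty acid oxidation genes fell in 21 of 28, with Acaa2 (-1.56) and Acadvl (-1.17). Contraction and calcium handling genes fell in 19 of 32, with Atp2a2, the calcium pump SERCA2 (-1.24), and Kcnip2 (-1.72), a potassium channel subunit. The genes with the smallest p were Fndc1 (1.88), Bnc2 (1.60), Basp1 (2.37), C1s1 (1.74), Myof (2.03) and Thbs3 (1.41) among those that rose. They were Cpeb3 (-1.32), Rragd (-1.08), Cyp2u1 (-1.03), Gmpr (-1.12), Tmem246 (-1.46) and Asb14 (-1.50) among those that fell.

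The median change of all genes in this comparison was 0.20, and camera compares each list with the other genes. Collagens had a median of 2.20 (camera adjusted p = 3.62e-18, adjusted p = 0.423 with an estimated correlation), and 41 rose adjusted over the list alone. Oxidative phosphorylation had -1.07 (1.96e-25, adjusted p = 0.301 with an estimated correlation), and 37 fell adjusted over the list alone. Fatty acid oxidation had -1.04 (3.62e-18, adjusted p = 0.301 with an estimated correlation), with 23 lower adjusted over the list alone. Cardiomyocyte genes had -0.80 (7.77e-15, adjusted p = 0.301 with an estimated correlation), with 22 lower adjusted over the list alone. Macrophage genes rose in 28 of 30 (28 adjusted over the list alone, median 1.37, camera adjusted p = 1.68e-09, adjusted p = 0.497 with an estimated correlation). Activated fibroblast genes rose in 19 of 22 (20 adjusted over the list alone, median 1.36, camera adjusted p = 6.27e-08, adjusted p = 0.308 with an estimated correlation). Cell cycle genes rose in 17 and fell in 1 of 28 (21 and 1 adjusted over the list alone, median 0.91, camera adjusted p = 0.000114, adjusted p = 0.497 with an estimated correlation). Epicardial genes rose in 9 of 12 (12 adjusted over the list alone, median 1.81, camera adjusted p = 0.000161, adjusted p = 0.497 with an estimated correlation).

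Lymphocyte genes rose in 12 of 16 (13 adjusted over the list alone), with the antibody genes Igkc (5.45), Ighm (4.31) and Jchain (3.30). The lymphocyte median was 1.27 (camera adjusted p = 1.92e-05, adjusted p = 0.301 with an estimated correlation). Secreted heart factors rose in 14 and fell in 1 of 25 (15 and 3 adjusted over the list alone, median 1.13, camera adjusted p = 0.00891, adjusted p = 0.497 with an estimated correlation). Stress genes rose in 7 and fell in 1 of 19 (7 and 1 adjusted over the list alone), with Nppa (2.84) and Sprr1a (4.61) up. The stress median was 0.82 (camera adjusted p = 0.0166, adjusted p = 0.497 with an estimated correlation). Adipocyte genes rose in 12 and fell in 1 of 19 (13 and 1 adjusted over the list alone), with Cfd, encoding adipsin (4.87), and Cidec (4.23), a lipid droplet protein, up. The adipocyte median was 1.78 (camera adjusted p = 0.000848, adjusted p = 0.497 with an estimated correlation). Lung genes rose in 6 and fell in 1 of 8 (6 and 1 adjusted over the list alone), with Scgb3a2 (5.51) up. The lung median was 2.87 (camera adjusted p = 0.0368, adjusted p = 0.605 with an estimated correlation). Scgb3a2 stood at 5.32, 48.7 and 54.8 in the MI+CIH libraries, at 0 to 0.17 in CIH and at 6.24 in sham 2.

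By limma 4368 genes changed (3088 rose, 1280 fell), of which 1249 rose and 318 fell by at least 1 on the log2 scale. The share that rose was 70.7%, or 49.5% of 4223 genes after median-of-ratios scaling, and the count was 2826 without MI+CIH 3 and 2291 without both sham 2 and MI+CIH 3. A fit of only the groups compared gave 1475 genes here and 1042 in MI vs sham. The size of the gap between 4368 here and 304 there thus depends on the spread shared by all groups.

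**Figure D2:**
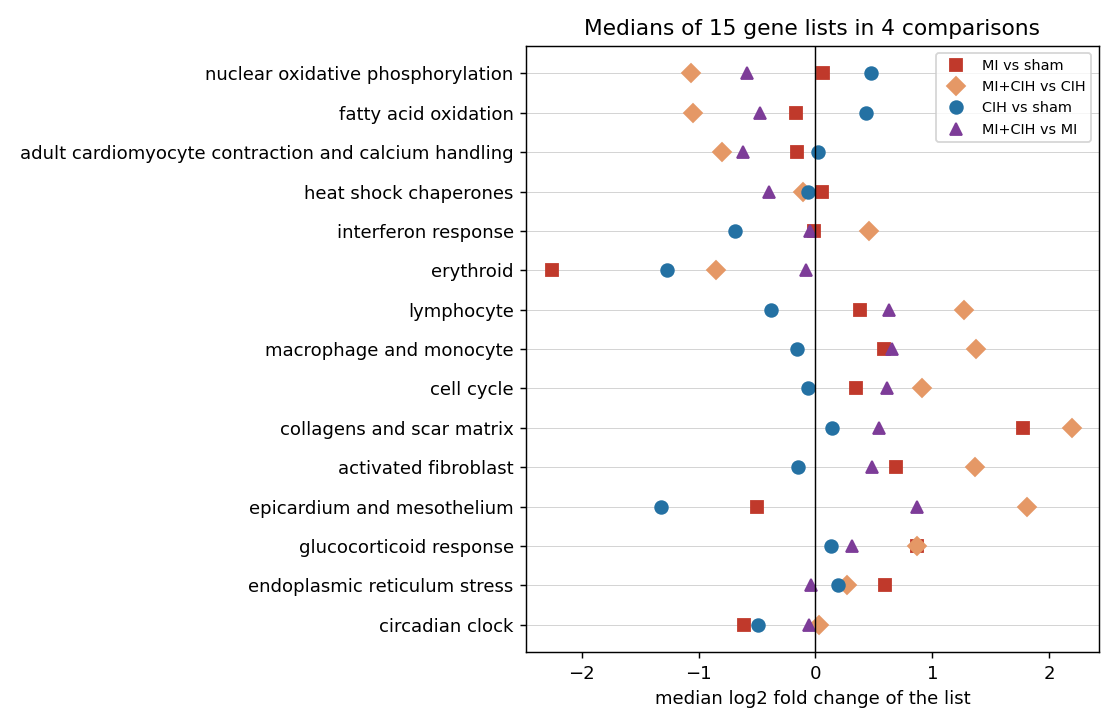
Median log2 fold change (horizontal axis) of the tested genes of 15 lists fixed before the data were examined, in MI vs sham, MI+CIH vs CIH, CIH vs sham and MI+CIH vs MI, 1 point per list and comparison. Collagens lie at 1.78 and 2.20 in the MI comparisons, and nuclear oxidative phosphorylation lies at 0.47 in CIH vs sham and -0.58 in MI+CIH vs MI.

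MI+CIH vs sham set both treatments against the control. Collagen and matrix genes rose in 39 of 42, with Col3a1 (3.62), Eln (2.99), Tnc (2.48) and Mfap5 (2.13), and macrophage genes in 23 of 30, with Ctss, the protease cathepsin S (2.49). Glucocorticoid response genes rose in 15 of 21, with Fkbp5 (2.50) and Tsc22d3 (1.21). Erythroid genes fell in 8 of 9, with Alas2, which starts haem synthesis in red cells (-2.78). Cardiomyocyte genes fell in 14 of 32, and oxidative phosphorylation genes in 11 of 41, with Sdha (-0.70). Cdkn1a rose by 2.60 and Fndc1 by 1.26, and Scn4b (-2.39), Hlf (-1.97), Mid1ip1 (-1.98), Wnk2 (-1.44), Cpeb3 (-1.29) and Adamts7 (-1.20) fell.

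The median of all genes was 0.12. The collagen median was 2.29 (camera adjusted p = 2.47e-26, adjusted p = 0.307 with an estimated correlation). The macrophage median was 1.22 (camera adjusted p = 7.21e-11, adjusted p = 0.309 with an estimated correlation). The glucocorticoid median was 1.34 (camera adjusted p = 3.92e-08, adjusted p = 0.307 with an estimated correlation). The erythroid median was -2.34 (camera adjusted p = 9.45e-09, adjusted p = 0.307 with an estimated correlation). The cardiomyocyte median was -0.78 (camera adjusted p = 5.6e-15, adjusted p = 0.307 with an estimated correlation). The oxidative phosphorylation median was -0.58 (camera adjusted p = 4.17e-13, adjusted p = 0.309 with an estimated correlation). Adjusted over the list alone 42 collagen, 28 macrophage and 18 glucocorticoid genes rose, and 8 erythroid, 22 cardiomyocyte and 20 oxidative phosphorylation genes fell. Clock genes rose in 4 and fell in 8 of 19 (4 and 10 adjusted over the list alone), with Arntl at 2.49 and Tef at -1.45. The clock median was -0.66 (camera adjusted p = 0.0036, adjusted p = 0.307 with an estimated correlation). Cell cycle genes rose in 15 and fell in 1 of 28 (21 and 2 adjusted over the list alone, median 0.92, camera adjusted p = 3.2e-06, adjusted p = 0.309 with an estimated correlation). Fatty acid oxidation genes rose in 1, Pdk4 (2.22), and fell in 12 of 28 (1 and 18 adjusted over the list alone, median -0.60, camera adjusted p = 8.69e-10, adjusted p = 0.307 with an estimated correlation). In the endoplasmic reticulum stress list 10 rose and 1 fell (15 and 1 adjusted over the list alone), the latter Ddit3 (-0.59). The reticulum stress median was 0.54 (camera adjusted p = 0.00087, adjusted p = 0.372 with an estimated correlation). Lists of tissues other than heart muscle moved with these. Adipocyte genes rose in 8 of 19 (12 adjusted over the list alone, median 1.23, camera adjusted p = 0.000444, adjusted p = 0.442 with an estimated correlation), with a median of 1.92 without both sham 2 and MI+CIH 3. Lung genes rose in 4 and fell in 1 of 8 (6 and 1 adjusted over the list alone, median 2.37, camera adjusted p = 0.0451, adjusted p = 0.604 with an estimated correlation), and sham 2 also held airway genes.

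By limma 2603 genes changed (1749 rose, 854 fell), and the share that rose was 67.2%, or 49.4% of 2815 genes after median-of-ratios scaling. The count was 976 without sham 1, 1366 without sham 2, 1642 without sham 3, 1261 without MI+CIH 3 and 563 without both sham 2 and MI+CIH 3.

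The interaction of MI and CIH asked whether hypoxia acted differently in infarcted and sham hearts. Ddit3 and Basp1, a membrane protein of growing cell processes, had the smallest adjusted p. Ddit3 fell with CIH in sham hearts (-1.23) and stood at 7.54 ± 0.656 in MI and 8.85 ± 1.07 in MI+CIH, an interaction of 1.45 (SE 0.18, adjusted p = 0.0396). Basp1 had an interaction of 2.37 (SE 0.30, 0.0396), and Csf1, the growth factor of macrophages, 1.46 (0.0486). Nuclear oxidative phosphorylation genes lay higher with CIH in sham hearts and lower with CIH in MI hearts, with a median interaction of -1.06 (camera adjusted p = 1.23e-25, adjusted p = 0.439 with an estimated correlation). Of 41 genes 33 were negative past the threshold adjusted over the list alone and 0 over all genes. Cox8b had an interaction of -2.50 (adjusted p = 0.0537).

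By limma 12 genes passed, 11 positive and 1 negative (Tmem246). The median interaction of all genes was 0.13, and after median-of-ratios scaling 151 genes passed, of which 41.1% were positive against 91.7% before. The count was 999 without MI+CIH 2, 110 without CIH 1, 94 without MI+CIH 1, and 0 without any 1 of sham 1, sham 2, MI 1, MI 2, MI 3, CIH 2, CIH 3 and MI+CIH 3 (3294 genes had an unadjusted p under 0.05, and voom gave 295, of which 95 were positive and 200 negative). It was 0 without both sham 2 and MI+CIH 3.

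Across the 15503 genes, which are not independent replicates, the MI effect without CIH and the MI effect under CIH correlated at Pearson r = 0.334 and Spearman rho = 0.324, with the same sign in 62.6% of genes. These comparisons share no library. Of the 212 genes that rose in MI vs sham 163 rose in MI+CIH vs CIH where 42.2 would if calls were independent, Col3a1 and Eln among them, and of the 92 that fell 42 fell where 7.6 would. Opposite calls were made for 5 genes. The CIH effect without MI and the CIH effect in MI hearts correlated at r = -0.220 and rho = -0.240, with the same sign in 39.7% of genes, and r was -0.139 without CIH 1 and -0.136 without sham 2.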

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

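The tests of other splits of the libraries and of the share of cardiomyocytes were chosen after the results were seen, and those of transcript length and ribosomal protein genes before. Each result below met 1 rule: the effect of CIH differed between hearts with and without MI by the interaction test. Of 100 regroupings that exchanged sham with CIH and MI with MI+CIH libraries 2 gave as many genes as the real 12, the real one included (highest other 20). With the common CIH effect of each gene removed first 1 of 100 gave as many, the real one (highest other 3). Both shares are under 0.05, but they were not adjusted over the tests of other splits, and the real count is 0 without any 1 of 8 libraries. They do not settle whether chance gave the gene count. For the lists 19 of 100 gave as many as the real 19 (highest other 22), so chance cannot be excluded.

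Nuclear oxidative phosphorylation genes had a median interaction of -1.06, with 0.47 for CIH vs sham and -0.58 for MI+CIH vs MI, while the 12 mitochondrially encoded genes had 0.42, -0.48 and -0.20 (camera adjusted p = 0.796, 0.252 and 0.082). A changed share of cardiomyocytes alone would move nuclear and cardiomyocyte genes alike, but in CIH vs sham the nuclear genes exceeded cardiomyocyte genes by a median of 0.448 (95% interval over genes 0.226 to 0.677). In MI+CIH vs MI macrophage genes exceeded endothelial genes by 0.924 (0.692 to 1.212), unlike a lower share with all other cell types up alike. Intervals of this kind, here and below, leave out the spread between libraries. The differences thus weigh against these explanations only for the libraries measured. Transcript length is argued against too: lists matched on exon length and level had a median interaction of -0.178 (central 95% of lists -0.445 to 0.079, 0% as low). The matched genes were drawn singly, without the correlation among oxidative phosphorylation genes. A bias on short abundant transcripts stays open, since 84 ribosomal protein genes had a median interaction of -0.35 with 56 below 0 and the share of FPKM in the short RNA Rpph1 moved as the pattern does (3.26 to 4.97% in sham, 5.1 to 9.26% in CIH, 5.28 to 6.52% in MI and 2.92 to 5.06% in MI+CIH), and a lower cardiomyocyte share together with a change in macrophages stays open in MI+CIH vs MI, where oxidative phosphorylation exceeded cardiomyocyte genes by 0.036 (-0.124 to 0.098), while in the interaction itself the difference was -0.392 (-0.764 to -0.155), which is away from 0 and counts against a cardiomyocyte share as its whole cause, though the interval reaches within the bound of 0.2 set for CIH vs sham. A different response of heart muscle to hypoxia after infarction and airway tissue in the MI+CIH samples stay open, neither of them tested here, and all of it rests on lists whose number other regroupings matched.

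Among single genes Ddit3 had an interaction of 1.45, Basp1 2.37, Nabp2 1.33, Bnc2 1.31, Upf3b 1.83, S100a11 1.89, Csf1 1.46, Maco1 0.97, Ankrd12 1.27, Pfkfb3 1.96 and Tmem246 -1.59. Mir5104 had 3.47, and as a small gene that may lie in a host gene it is uncertain. All 12 had limma adjusted p from 0.0396 to 0.0495 with all 12 libraries. The number passing was 0 without any 1 of sham 1, sham 2, MI 1, MI 2, MI 3, CIH 2, CIH 3 and MI+CIH 3, and 94, 110 and 999 without MI+CIH 1, CIH 1 and MI+CIH 2 (3294 had an unadjusted p under 0.05).

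Among lists, the fatty acid oxidation median was -0.89 (camera adjusted p = 5.74e-15, adjusted p = 0.439 with an estimated correlation). The cardiomyocyte median was -0.66 (camera adjusted p = 2.64e-07, adjusted p = 0.553 with an estimated correlation). The heat shock median was -0.44 (camera adjusted p = 0.000717, adjusted p = 0.553 with an estimated correlation). The endothelial median was -0.26 (camera adjusted p = 0.00086, adjusted p = 0.553 with an estimated correlation). The HIF target median was -0.25 (camera adjusted p = 0.00259, adjusted p = 0.553 with an estimated correlation). The reticulum stress median was -0.34 (camera adjusted p = 0.00276, adjusted p = 0.666 with an estimated correlation). The epicardial median was 2.49 (camera adjusted p = 2.93e-07, adjusted p = 0.553 with an estimated correlation). The lymphocyte median was 1.29 (camera adjusted p = 4.23e-05, adjusted p = 0.439 with an estimated correlation). The interferon median was 0.57 (camera adjusted p = 4.23e-05, adjusted p = 0.666 with an estimated correlation). The cytokine median was 0.90 (camera adjusted p = 0.00011, adjusted p = 0.563 with an estimated correlation). The macrophage median was 0.82 (camera adjusted p = 0.000144, adjusted p = 0.666 with an estimated correlation). The cell cycle median was 0.64 (camera adjusted p = 0.00164, adjusted p = 0.666 with an estimated correlation). The NADPH oxidase median was 0.74 (camera adjusted p = 0.0256, adjusted p = 0.666 with an estimated correlation). The fibroblast median was 0.67 (camera adjusted p = 0.03, adjusted p = 0.666 with an estimated correlation). The lung median was 3.36 (camera adjusted p = 0.00164, adjusted p = 0.666 with an estimated correlation). The neutrophil median was 2.13 (camera adjusted p = 0.0342, adjusted p = 0.666 with an estimated correlation). The erythroid median was 1.51 (camera adjusted p = 0.0437, adjusted p = 0.759 with an estimated correlation). The adipocyte median was 0.83 (camera adjusted p = 0.0495, adjusted p = 0.778 with an estimated correlation). Without both sham 2 and MI+CIH 3 the neutrophil median was lower by over 1.5 times, the interferon median was 0.86 and the heat shock median -0.23. Adjusted over the list alone 17 fatty acid oxidation and 12 cardiomyocyte genes were negative and 11 epicardial and 7 lymphocyte genes positive, against 0 over all genes in these lists. In the same way 7 lung, 7 cytokine, 5 interferon, 4 macrophage, 4 fibroblast, 2 cell cycle and 1 erythroid genes were positive and 7 HIF target, 5 endothelial, 5 reticulum stress and 1 heat shock genes negative, where Csf1, Ddit3 and Pfkfb3 passed over all genes, and 1 to 2 genes of 5 lists had the other sign.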

How the results depend on the processing

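The median-of-ratios scaling, the fit without sham 2 and MI+CIH 3, and limma voom on the recovered reads were added after seeing the data, and the other alternatives were planned. The alternatives meant for counts (TMM against size factors, and a Wald test) were not run, since the values are FPKM. The naming rule picked a set larger than the genes in the text, with 378 calls and 255 values without a call. None of the 18 to 21 alternatives run on each gene reversed the sign of a call. Changes of sign were not counted for values without a call. Of the calls 169 passed under each alternative run on them, and of the other values 158 never passed. By comparison 11 of 53 calls held in MI vs sham, 0 of 1 in CIH vs sham, 0 of 51 in MI+CIH vs MI, 103 of 139 in MI+CIH vs CIH, 55 of 122 in MI+CIH vs sham and 0 of 12 in the interaction. Cdkn1a in MI vs sham held in the 20 alternatives run on it (log2 3.19 to 3.35).

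Without a filter 143 genes passed in MI vs sham, 82 in MI+CIH vs MI and 1 in the interaction, and with a mean of at least 1 FPKM 12 in MI+CIH vs MI. A fit of only the groups compared gave 1042 in MI vs sham, 0 in CIH vs sham, 0 in MI+CIH vs MI, 1475 in MI+CIH vs CIH and 1173 in MI+CIH vs sham, each spread then resting on fewer libraries. A pseudocount of 0.1 gave 0 in MI+CIH vs MI and 2 in the interaction. A minimum log2 change of 1 left 177 in MI vs sham, 1567 in MI+CIH vs CIH and 981 in MI+CIH vs sham by construction. Median-of-ratios scaling gave 151 in the interaction. Without sham 2 and MI+CIH 3 there were 65 in MI vs sham, 0 in CIH vs sham, 10 in MI+CIH vs MI, 2291 in MI+CIH vs CIH, 563 in MI+CIH vs sham and 0 in the interaction, and the correlation of the CIH effects was -0.139. Voom gave 16 in CIH vs sham, 206 in MI+CIH vs MI and 295 in the interaction. Except where construction is named, the cause was not tested.

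The replicate number as a block gave 177 genes in MI vs sham, 0 in CIH vs sham, 14 in MI+CIH vs MI and 0 in the interaction. Libraries of the same number correlated at -0.175 to 0.128 after removing group means (mean -0.018), with 3 of 18 such pairs above 0.1. The best match had the same number for 5 libraries. No strong pairing by number was seen, but a weaker one cannot be excluded in this way.

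Of 37 lists 0 passed with an estimated correlation in each of the 6 comparisons, where camera with the preset gave 18, 12, 20, 22, 22 and 19. Fry gave 7 in MI vs sham, 0 in CIH vs sham, 0 in MI+CIH vs MI, 21 in MI+CIH vs CIH, 20 in MI+CIH vs sham and 4 in the interaction. Without sham 2 and MI+CIH 3 the medians of lists that passed camera moved by over 1.5 times in 0 of 18, 2 of 12, 9 of 20, 3 of 22, 3 of 22 and 3 of 19 cases, none of them changing sign.

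Leaving out 1 library gave 22 to 484 genes in MI vs sham, 0 to 124 in CIH vs sham, 0 to 1029 in MI+CIH vs MI, 2826 to 4590 in MI+CIH vs CIH, 976 to 3035 in MI+CIH vs sham and 0 to 999 in the interaction. It gave 17 to 21, 11 to 16, 16 to 22, 19 to 23, 21 to 23 and 15 to 24 lists. The correlation of the MI effects was 0.280 to 0.389 and that of the CIH effects -0.250 to -0.136. A 2-fold change was recovered in 48% of simulated genes in MI vs sham and in 15% for the interaction, so many changes of that size or less would be missed with 3 libraries per group.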

Other observations

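The tests of the clock genes and of other splits of the libraries were chosen after the results were seen, as was the permutation within groups, and those of airway markers before.

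Members of the nerve, skeletal muscle, MHC class II and smooth muscle lists changed in MI+CIH hearts against CIH. Of 14 nerve genes 4 rose (4 adjusted over the list alone), with the myelin gene Mbp (1.24), and the camera test did not pass (adjusted p = 0.502). MHC class II and dendritic cell genes rose in 7 of 15 (8 adjusted over the list alone, median 0.78, camera adjusted p = 0.00869, adjusted p = 0.497 with an estimated correlation), with H2-Oa (1.22) and H2-DMb2 (1.20). NADPH oxidase genes rose in 6 of 8 (7 adjusted over the list alone, median 1.39, camera adjusted p = 0.00201, adjusted p = 0.497 with an estimated correlation), with Nox4 (2.34), a producer of hydrogen peroxide, and the phagocyte subunit gene Ncf1 (1.59). Smooth muscle and pericyte genes went both ways, 6 up and 3 down of 17 (7 and 4 adjusted over the list alone), with the contractile gene Lmod1 (1.70) up and the pericyte channel genes Abcc9 (-0.92) and Kcnj8 (-0.76) down (camera adjusted p = 0.668). Skeletal muscle genes rose in 4 and fell in 1 of 14 (5 and 1 adjusted over the list alone, camera adjusted p = 0.127), with Tnnt3 at 4.28. Myh4 stood at 0.0957, 2.91 and 11.4 in the MI+CIH libraries.

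In the oxidative stress list 10 genes rose and 2 fell of 23 in MI+CIH vs CIH (10 and 2 adjusted over the list alone, camera adjusted p = 0.354), with the extracellular superoxide dismutase gene Sod3 up (1.63) and the mitochondrial Sod2 down (-1.04). Renin and adrenergic genes split evenly, 4 up and 4 down of 16 (4 and 4 adjusted over the list alone, camera adjusted p = 0.855), with Ace (1.43) and Agt (1.90) up and Adrb1 (-1.32) and Agtr1a (-0.90) down. In the C1q and TNF related family 6 of 11 rose (6 adjusted over the list alone, camera adjusted p = 0.272), with C1qtnf3 (1.78) and C1qtnf6 (1.73), while C1qtnf9 did not pass.

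Airway genes were higher in MI+CIH than in MI, where 5 of 10 secretory-cell markers and 0 of 13 tested ciliated-cell markers passed over all genes. The ciliated-cell set did not hold the cilia gene Foxj1, which passed. Over the 12 libraries, centred within groups, the means of 22 ciliated-cell and 10 secretory-cell markers correlated at Pearson r = 0.839 (exact permutation p = 0.00463, Benjamini-Hochberg 0.0139 in a family of 3), Spearman rho = 0.944 (p = 0.0139) and r = 0.958 without MI+CIH 1 and 2, so airway tissue sampled with some hearts may account for these genes. Centring was not redone for the r without MI+CIH 1 and 2. MI+CIH 3 thus kept a deviation that those libraries helped to set, and this r is no separate check. In MI hearts 4 of the 22 and 3 of the 10 markers had a mean of 0.5 FPKM or more, 0 and 3 are in the fixed lists, and sham 2, which had no MI and no CIH, was above both other shams in 18 and 10 of them, with Scgb1a1 at 485 and Bpifb1 at 7.47. Airway wall with cartilage cannot be told apart from airway lining alone, as ciliated and cartilage markers correlated at r = 0.555 (exact permutation p = 0.242, adjusted 0.242), rho = 0.524 (p = 0.109) and 0.109 without MI+CIH 1 and 2. Sftpc, a surfactant gene of the lung list, stood at 216 in MI+CIH 2, at 14.5 in sham 2 and at 0 to 0.311 in the other libraries. Lung tissue other than airway in MI+CIH 2 and sham 2 was not tested and is not excluded. A response of the heart to MI with CIH also stays open for part of the rise, since 3 of 3 MI+CIH libraries lay above all 9 others in ciliated markers, MI+CIH 1 only narrowly (0.468 against 0.451 in sham 2), which airway tissue in those samples would give too.

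Clock genes differed between MI and sham. Across the 19 clock genes the MI effect under CIH correlated with that without CIH at r = 0.788 (permutation p = 4e-05, genes not independent). The slope was 0.242 (95% interval over genes 0.148 to 0.323, 0.076 to 0.464 leaving out 1 library), so the effect measured under CIH was smaller. The interval leaves out the spread between libraries, and the CIH libraries differed among themselves, so the slope cannot decide whether the MI effect depends on CIH. In MI+CIH vs CIH the list median was 0.03 with 1 of 19 lower and 0 higher over all genes, and the median interaction was 0.66 (camera adjusted p = 0.173, 7 positive and 2 negative adjusted over the list alone). Time of day at collection cannot be told apart from an MI effect, whether or not CIH alters it. The Arntl and Dbp arms of the clock, centred within groups, correlated over the 12 libraries at r = -0.841 and rho = -0.287. The exact permutation gave p = 0.186 for r (adjusted 0.242) and p = 0.511 for rho. The unrestricted permutation, replaced after its result was seen, had given p = 0.0104 for r. The mean of the Arntl arm ranged from 1.158 to 2.572 in CIH. It ranged from 1.131 to 1.271 in sham, 3.128 to 3.316 in MI and 2.52 to 2.842 in MI+CIH. Mainly the order of the CIH libraries could thus alter r, so the exact test could hardly give a small p. Without CIH 2 and 3 r was 0.244, so the relation rests on those libraries and neither p-value decides. The labels give no collection time, and the CIH libraries differed in Dbp, at 27.5, 7.77 and 73.3.

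Of the 10 splits of 6 libraries, which are too few for a share under 0.05, 1 gave as many genes as the real 304 in MI vs sham (highest other 1), 1 as the real 1 in CIH vs sham (0), 1 as the real 51 in MI+CIH vs MI (6), 1 as the real 4368 in MI+CIH vs CIH (1) and 1 as the real 2603 in MI+CIH vs sham (1), the real split included. For lists the numbers were 2 of 10 in MI vs sham (real 18, highest other 18), 4 in CIH vs sham (12 and 16), 2 in MI+CIH vs MI (20 and 20), 1 in MI+CIH vs CIH (22 and 21) and 1 in MI+CIH vs sham (22 and 21). Of 100 regroupings of the 12 libraries 4 gave a correlation of the MI effects as far from 0 as 0.334 (highest other 0.369 in size) and 3 one of the CIH effects as far as -0.220 (0.228). Exchanging all labels within 1 pair of groups turns only the sign of r, so some regroupings repeat others in size. Both shares are under 0.05 but close to it, and they were not adjusted over the tests of other splits. They do not settle whether chance gave either correlation.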
